A study of Mus musculus with 26 samples.

How the data were processed

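Colon RNA of 26 mice was measured by paired-end sequencing of 150 bp reads on an Illumina NovaSeq after poly-A selection, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with fastp, aligned to GRCm38 (mm10) with HISAT2 2.2.1 and counted per gene with featureCounts 2.0.6. The deposited table holds raw gene counts, 1 column per mouse, for 54532 genes. The notes give no annotation release, no strand setting and no rule for reads that map to several places. The time of day of collection, the cage and the sequencing batch of each mouse are not given in the sources used here. Gene identifiers, names and coordinates are those of the deposited table. Of its genes, 54409 were shared with an annotation of the same build, and 53499 of them, 98.3 %, had the same start and end in both. 100 gene names stand on more than 1 line of the table, so genes were followed by identifier.

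The mice formed 3 groups: 8 normal control, 8 loperamide and 10 loperamide plus R. mucilaginosa. Each library came from a separate mouse, per the labels, so the p-values refer to differences between mice. Total counts ran from 14.0 to 21.3 M (M, 1e6) per mouse, with a median of 14.8 M. The 3 pairwise comparisons, their tests, the gene lists, the rule for named genes and the other settings were fixed before the data were examined.

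Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with the group as factor, which left 16868, and libraries were scaled by trimmed mean of M values. A quasi-likelihood model with robust dispersion was fitted to all 26 mice with 1 mean per group and no covariate. Each comparison was tested two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM are counts per 1e6 of the scaled library size, and list scores are the mean over a list's measured genes of log2 CPM with a prior count of 2. Values are given as mean ± SD over mice and log2 fold changes ± their standard error (SE).

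The 44 gene lists cover neuroactive systems, cell types, neighbouring tissues, position along the colon and metabolic or stress responses. Each was tested against all other genes with edgeR's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 44 lists of a comparison. List scores were compared between groups by two-sided exact permutation tests over all splits of the mice, adjusted over the same lists. Counts of list members past the threshold are also given adjusted over the list alone. The named genes were, per comparison, the 10 largest changes in each direction among genes past the threshold with a proper name and a mean of at least 1 CPM, up to 4 genes past the threshold with the smallest p in each list, and 24 key genes of gut movement, fluid, mucus, barrier and inflammation. Where fewer than 10 genes passed, all of these and the 5 smallest p in each direction were taken, the latter as values only.

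For a return of loperamide changes, the number of genes called in both steps was counted and the log2 fold changes of both steps were correlated across genes. Both steps share the loperamide mice, so the same values were computed on 20 simulated sets with no effect and on 70 splits of the loperamide mice that gave each step its own 4. Library totals, detected genes, the mitochondrial share and the share of the 10 most abundant genes were compared by two-sided exact permutation tests.

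The other settings were other scalings, no filter and a stricter one, DESeq2 1.42.0, limma 3.58.1 with voom and quality weights, fits of 2 groups only, a replicate block, composition covariates, other thresholds and each mouse left out in turn. After the data were seen, a position covariate, comparisons within mice of 1 position type and fits without 3 mice were added. Position type was set by a ratio of at least 5 between the counts of Hoxa13 and Osr2, in either direction. The genes called in each comparison were set against 100 splits of the same mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.

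The fits were tested on simulated counts with 200 changed genes among those tested, 67 or 66 at each size. For loperamide against normal control, 47.8 % of the 1.5-fold, 59.7 % of the 2-fold and 93.9 % of the 4-fold changes were recovered among 16701 genes. For R. mucilaginosa plus loperamide against loperamide the shares were 55.2 %, 85.1 % and 95.5 % of 16701 genes. Against normal control they were 58.2 %, 85.1 % and 93.9 % of 16710 genes. No sample and no per-sample column of the table was left out of the main comparisons. The smallest chi-square per degree of freedom between libraries of a group was 9.69, so no library was a copy of another in its group. Libraries of different groups were not compared in this way.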

Results

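Gene counts of the colon were obtained from 26 male C57BL/6 mice, 6 weeks old before acclimatization. Loperamide, an agonist of the mu-opioid receptor that slows the gut, was given to 18 of them by gavage, at 10 mg/kg on days 8 to 14 and at 15 mg/kg on days 15 to 40. Of these, 10 also received Rothia mucilaginosa, a bacterium of the mouth and airways, at 2e8 CFU per day on days 22 to 40. The other 8 loperamide mice and the 8 normal control mice received the carrier. Mean totals were 15.5 ± 2.38 M counts (M, 1e6; SD, n = 8) in normal control, 15.5 ± 1.12 M (n = 8) under loperamide and 14.9 ± 0.767 M (n = 10) with R. mucilaginosa. By exact permutation test, more genes were detected with R. mucilaginosa than in normal control, by 331 genes (p = 0.0172), and the 10 most abundant genes took a smaller share of the counts, by -1.39 percentage points (p = 0.00432). The other 10 of these 12 depth comparisons gave exact p of 0.0981 or more.

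The colon samples came from unlike stretches of the organ, and this split ran through every group. Hoxa13 and Hoxb13, homeobox genes of the hindgut's far end, and Insl5, a peptide of distal colon endocrine cells, were high in 9 mice and low or not found in 15. Hoxa13 lay at 51.3 to 65.3 CPM in the 9 mice, called distal-type here, and at 0 to 8.77 CPM in the 15, called proximal-type. Osr2, a transcription factor gene, lay at 0.344 to 2.42 and at 59.2 to 141 CPM in the same mice. Another 2 mice fell between. Aqp4, a water channel, was at 657 to 1070 CPM in distal-type and 29.2 to 231 CPM in proximal-type mice. Hoxd10 and Hoxd11, listed beforehand as distal genes, were higher in the proximal-type mice. The first principal component, with 27.7 % of the variance, separated these types. Normal control and loperamide each held 4 distal-type and 4 proximal-type mice, and R. mucilaginosa held 1 distal-type, 2 intermediate and 7 proximal-type mice (Fisher's exact p = 0.118 against each). Values within proximal-type mice are therefore given beside the main ones. These mice were still not fully matched. Their position index, the log2 ratio of Hoxa13 to Osr2, was on average higher with R. mucilaginosa by 1.78 than under loperamide and by 0.62 than in normal control. Its ranges overlapped: -6.36 to -3.15, -10.02 to -5.45 and -5.93 to -5.08. The first component, with r = 0.96 to this index over all 26 mice, ran from -16.6 to -0.75, -40.13 to -21.95 and -24.94 to -16.23. Within the type it need not follow position: loperamide mouse 5 and R. mucilaginosa mouse 6 had an index of -5.99 and -6.12, but lay at -40.13 and -14.44.

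**Figure D1:**
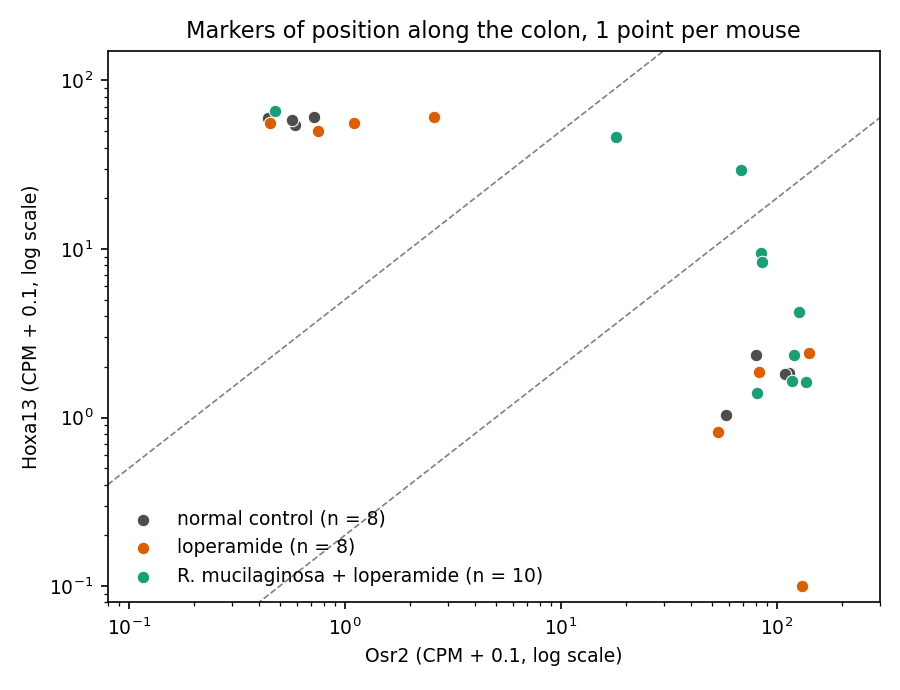
Hoxa13 against Osr2, in CPM plus 0.1 on log scales, 1 point per mouse coloured by group; the dashed lines mark a ratio of 5 in either direction. Hoxa13 is at 51.3 CPM or more in the 9 mice at upper left and at 8.77 CPM or less in the 15 at lower right.

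The comparison of loperamide with normal control asks what the constipation model did to the colon. Transcripts of enteric neurons, the nerve cells that drive gut movement, were lower under loperamide: the median log2 fold change was -0.37 and 23 of 23 genes were negative (adjusted p = 6.33e-05). Peptide and nitrergic motor transmitters, the signals of those neurons, had a median of -0.26 (adjusted p = 0.00112). Goblet cell and mucus genes (-0.16, adjusted p = 0.00935) and antimicrobial defence genes (-0.25, adjusted p = 0.0112) were also lower. Interferon response genes, induced by antiviral signals, had a median of 0.79, with 20 of 22 genes positive (adjusted p = 0.0112). Stem cell genes (0.10, adjusted p = 0.0129) were higher by a small amount. Circadian clock genes had a median of 0.13 (adjusted p = 0.0267) over genes that moved in opposite directions. Per2 stood at 0.84 and Per3 at 0.57, against Npas2 at -0.57 and Nfil3 at -0.76, none of them past the threshold. Mitochondrially encoded (-0.28, adjusted p = 0.00752), skeletal muscle (-0.28, adjusted p = 0.0122) and cholesterol synthesis genes (-0.12, adjusted p = 0.0376) completed the 10 of 44 lists called. Of the 14 skeletal muscle genes listed, only 5 had enough counts to be tested. Skeletal muscle lost its call under a stricter filter (-0.21, adjusted p = 0.511) and cholesterol synthesis with a position covariate (-0.10, adjusted p = 0.0871). None of the 10 held with an estimated correlation, where the smallest adjusted p was 0.371, and 0 lists passed by their scores.

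The neuron and interferon calls depended on single mice. Loperamide mouse 6 had the lowest smooth muscle score of its group, 4.91, and a neuron score of 0.12. Without it the neuron list had a median of -0.25 (adjusted p = 0.0575) and the transmitter list -0.15 (adjusted p = 0.114). Without loperamide mice 5 and 6 and normal control mouse 1 the neuron and transmitter lists stood at -0.05 (adjusted p = 0.878) and -0.01 (adjusted p = 0.951). Loperamide mice 5 and 6 were chosen for low neuron scores, so the choice itself favoured these smaller medians. The neuron score was 2.50 ± 0.71 (SD, n = 8) in normal control and 2.02 ± 0.97 (n = 8) under loperamide. Without loperamide mouse 8 the interferon median turned to -0.04, and without normal control mouse 1, which had the largest mitochondrial share, the mitochondrial median was -0.05 (adjusted p = 0.401). Skeletal muscle was not called without loperamide mouse 6 (-0.29, adjusted p = 0.0575), nor goblet cells without loperamide mouse 2 (-0.09, adjusted p = 0.0942) or 5 (-0.07, adjusted p = 0.085). Stem cells were not called without normal control mouse 7 or loperamide mouse 4 (0.09 each, adjusted p = 0.053 and 0.0512). Interferon was also not called without normal control mouse 6, 7 or 8 (0.73, 0.72 and 0.66). The clock call was lost without normal control mouse 1, 3 or 8 or loperamide mouse 2 or 5 (medians 0.10 to 0.18), and cholesterol synthesis without normal control mouse 3, 5 or 8 or loperamide mouse 2, 5, 6 or 8 (-0.09 to -0.03), while antimicrobial defence kept its call in all 16 fits. Among proximal-type mice, 4 against 4, the neuron median was -0.66 (adjusted p = 3.39e-06, but 0.642 with an estimated correlation), transmitters -0.50, antimicrobial defence -0.29 and cholesterol synthesis -0.37 (adjusted p of 0.566 to 0.614 with an estimated correlation). Without the same 3 mice, which left loperamide mice 2 and 8 against normal control mice 4, 5 and 7, the neuron median of the proximal-type mice turned to 0.33 (adjusted p = 0.0149) and the transmitter median to 0.22 (adjusted p = 0.235). The choice by neuron score favoured this turn too, so no conclusion on loperamide is drawn from it.

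No single gene passed the threshold between loperamide and normal control with edgeR, where 1198 genes had an unadjusted p under 0.05 against 843 expected by chance. DESeq2 called 9 genes and limma 0. As values only, Map2k6, a kinase of the stress-activated p38 pathway, had a log2 fold change of 0.45 ± 0.10 (SE), and Hsph1, a heat shock chaperone, 0.87 ± 0.21. Zc3h12a, an RNase that degrades inflammatory transcripts, had -0.97 ± 0.22, Pde10a, a cyclic nucleotide phosphodiesterase, -0.90 ± 0.20, and Gk, glycerol kinase, -0.69 ± 0.16. Nfil3, a repressor in the clock's output, had -0.76 ± 0.19 and Tox3 -0.52 ± 0.13, while L3mbtl3 had 0.45 ± 0.11, Cys1 0.63 ± 0.15 and Hdac4 0.42 ± 0.10. All 10 had an adjusted p = 0.365. Without normal control mouse 6, the edgeR fit called 3 genes: Zc3h12a (-1.10, adjusted p = 0.0159), Gk (-0.79, adjusted p = 0.0239) and Arhgap39 (0.47, adjusted p = 0.0173), the last named after its values were seen. Without loperamide mouse 8 it called Map2k6 alone (0.52, adjusted p = 0.0448). Within distal-type mice it called only Tef, a clock output gene (0.84, adjusted p = 0.0191), and within proximal-type mice 0 genes, with 1538 at an unadjusted p under 0.05. The loperamide change differed between both types for 0 genes (smallest adjusted p = 0.998, 613 at an unadjusted p under 0.05).

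The comparison of R. mucilaginosa plus loperamide with loperamide asks what the bacterium did in the model. Enteric neuron genes were higher with R. mucilaginosa, with a median of 0.46 and 22 of 23 genes positive (adjusted p = 1.32e-06, but 0.669 with an estimated correlation, at which none of the lists of this comparison held). Other parts of the gut's nerve and pacemaker apparatus had higher medians too: peptide and nitrergic transmitters 0.28 (adjusted p = 0.000364), the opioid system 0.28, the cholinergic system 0.29, other neuroactive receptors 0.17 and enteric glia 0.25 (adjusted p = 0.00733 each), and interstitial pacemaker cells 0.21 (adjusted p = 0.0104). Genes of endothelium (0.22, adjusted p = 0.000211), skeletal muscle (0.58, adjusted p = 0.00323), fibroblasts (0.13, adjusted p = 0.0104), macrophages (0.14, adjusted p = 0.0124), B cells (0.20, adjusted p = 0.0291) and T cells (0.12, adjusted p = 0.0353) were also higher. Epithelial genes went the other way: pan-epithelium -0.13 (adjusted p = 0.00287), fatty acid oxidation -0.18 (adjusted p = 0.00468), oxidative phosphorylation -0.10 (adjusted p = 0.00733) and tight junctions -0.08 (adjusted p = 0.0199). The smooth muscle contractile list, whose cells share the gut wall with the neurons, was not called (-0.05, adjusted p = 0.371). The skeletal muscle call rests on 5 measured genes of the 14 listed.

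These 17 lists did not hold with an estimated correlation (smallest adjusted p = 0.158 with an estimated correlation), and 0 passed by their scores (smallest adjusted p = 0.108, exact permutation). With covariates for muscle against epithelium and for position, 12 lists were called, 9 of them the same: neurons fell to 0.15 (adjusted p = 0.0342), and the calls of transmitters (0.15), the opioid system (0.08), the cholinergic system (0.21) and pacemaker cells (0.04, adjusted p = 0.182 each), other neuroactive receptors (0.09, adjusted p = 0.191) glia (0.07, adjusted p = 0.685), tight junctions (-0.06, adjusted p = 0.123) and fibroblasts (0.05, adjusted p = 0.515) were lost. A position covariate alone lost T cells (0.19, adjusted p = 0.176) and macrophages (0.12, adjusted p = 0.0993). Without loperamide mice 5 and 6 and normal control mouse 1, 8 lists were called, 4 of them the same, T cells, macrophages, skeletal muscle and endothelium, while neurons stood at 0.19 (adjusted p = 0.34), transmitters at 0.07 (adjusted p = 0.706) and the other 5 nerve and pacemaker lists at 0.08 to 0.16, none called. Loperamide mice 5 and 6 were chosen for low neuron scores, so the choice itself favoured smaller nerve medians without them. A stricter filter lost skeletal muscle (0.23, adjusted p = 0.104), B cells (0.18, adjusted p = 0.0568) and T cells (0.12, adjusted p = 0.0524). Without loperamide mouse 6 alone, glia (0.15, adjusted p = 0.167), fibroblasts (0.06, adjusted p = 0.218) and tight junctions (-0.07, adjusted p = 0.106) were lost. Fibroblasts were also lost without R. mucilaginosa mouse 4 (0.09), as were tight junctions (-0.07). Fatty acid oxidation (-0.04, adjusted p = 0.391) and oxidative phosphorylation (-0.04, adjusted p = 0.248) were lost without loperamide mouse 5, and fatty acid oxidation without loperamide mouse 2 (-0.14). B cells were lost without loperamide mouse 4, 5 or 7 or R. mucilaginosa mouse 1, 2 or 8 (0.15 to 0.19), T cells without loperamide mouse 1, 3, 4 or 7 or R. mucilaginosa mouse 1, 2 or 6 (0.02 to 0.13), and macrophages without loperamide mouse 3 or 4 or R. mucilaginosa mouse 2 or 4 (0.11 to 0.12). Neurons, transmitters, the opioid and cholinergic systems, other neuroactive receptors, pacemaker cells, pan-epithelium, skeletal muscle and endothelium kept their calls in all 18 fits with 1 mouse left out. Among proximal-type mice, 7 against 4, neurons had a median of 0.94 (adjusted p = 1.07e-09), transmitters 0.72 and smooth muscle contraction 0.62 (adjusted p = 1.04e-08), and T cells turned to -0.35. Without the same 3 mice neurons among these were at 0.29 (adjusted p = 0.0423) and transmitters at 0.40 (adjusted p = 0.0082). None of the 22 lists called there held, with a smallest adjusted p = 0.187 with an estimated correlation.

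**Figure D2:**
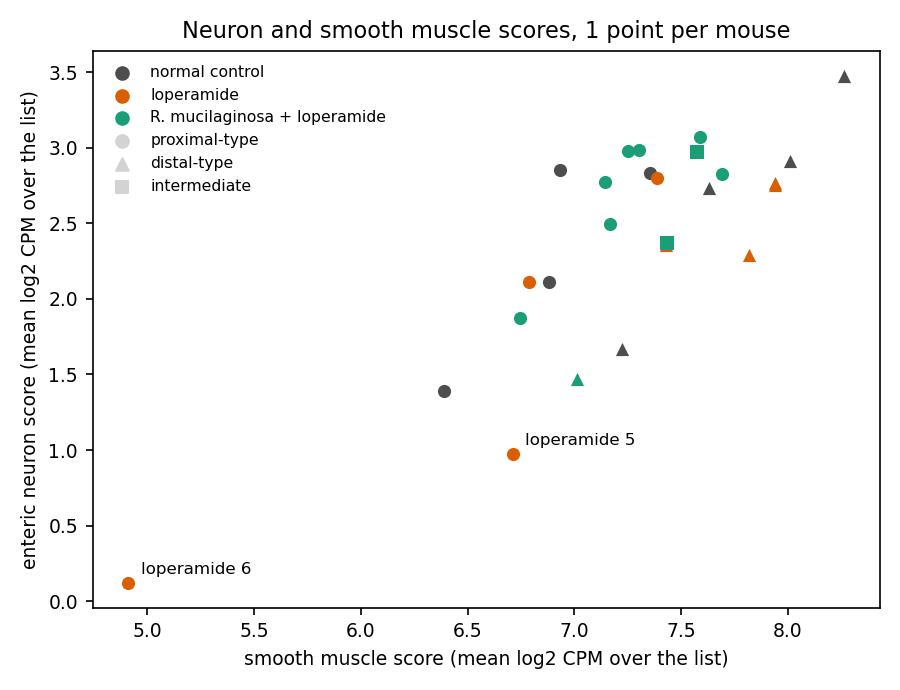
Enteric neuron score against smooth muscle score, each the mean log2 CPM over its list, 1 point per mouse with colour for group and shape for position type. Loperamide mouse 6, at 4.91 for muscle and 0.12 for neurons, lies apart from the other mice.

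Gene by gene, edgeR called 0 genes between R. mucilaginosa plus loperamide and loperamide, with 1423 at an unadjusted p under 0.05, while DESeq2 called 4 and limma 0. The 4 were Skil, Rogdi, Tspan4 and Actr3b (adjusted p = 0.0195 each), the last named after its values were seen. As values only, Skil, a repressor of TGF-beta signalling, had a log2 fold change of -0.58 ± 0.12 (SE), Tspan4 0.57 ± 0.12 and Rogdi 0.45 ± 0.09 (adjusted p = 0.34 each in edgeR). Arntl, the core clock activator also called Bmal1, had -0.69 ± 0.16, Usp53, a tight junction protein, -0.37 ± 0.09, Spred2, an inhibitor of the ERK pathway, -0.28 ± 0.07, and Mcur1, a mitochondrial calcium regulator, -0.23 ± 0.05. Cygb, a globin of fibroblasts, had 0.38 ± 0.09, Ddx41 0.18 ± 0.05 and Tram1l1 0.81 ± 0.22 (adjusted p = 0.543 for these 7).

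Among proximal-type mice alone, 7 against 4, the same comparison called 669 genes, 197 higher and 472 lower with R. mucilaginosa. With the position index as a covariate it called 9, all among the 669: the median log2 fold change of the 669 went from 0.51 to 0.49 in the same direction, while the median SE rose from 0.12 to 0.14. Arntl (-0.79 ± 0.16, adjusted p = 0.0184) and its partner Npas2 (-0.76 ± 0.17, adjusted p = 0.0244) fell, and the clock output genes Hlf (0.62 ± 0.12, adjusted p = 0.0184) and Dbp (0.60 ± 0.17, adjusted p = 0.0457) rose. Epithelial genes that fell were Krt20, a keratin of mature colonocytes (-0.78 ± 0.22, adjusted p = 0.0497), Vil1, a microvillus protein (-0.54 ± 0.14, adjusted p = 0.0371), and Cpt2, an enzyme of fatty acid oxidation (-0.45 ± 0.10, adjusted p = 0.0225). The nitric oxide receptor subunits Gucy1a1 (0.73 ± 0.18, adjusted p = 0.0312) and Gucy1b1 (0.70 ± 0.17, adjusted p = 0.0296), the glial factor Foxd3 (1.55 ± 0.42, adjusted p = 0.0413) and the collagen Col6a1 (0.52 ± 0.11, adjusted p = 0.0203) rose. With loperamide mice 5 and 6 left out the same comparison called 0 genes, with 1496 at an unadjusted p under 0.05. The other 5 pairs of these 4 loperamide mice, left out in turn, gave from 0 to 2087 genes.

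The comparison of R. mucilaginosa plus loperamide with normal control asks how far the treated colon stood from the untreated one. Of the 44 lists, the circadian clock had the most genes past the threshold, 10 of 17 measured, 7 higher and 3 lower, and 12 when adjusted over the list alone. Arntl (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126), the core clock activator, fell from 24.9 ± 8.25 CPM (SD, n = 8) to 11.6 ± 2.04 CPM (n = 10), a log2 fold change of -1.10 ± 0.16 (SE, adjusted p = 0.00143). Its partner Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236) fell from 19.7 ± 3.16 to 9.30 ± 1.93 CPM (-1.08 ± 0.16, adjusted p = 0.00143). Per genes and output genes rose: Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) from 31.6 ± 10.9 to 67.2 ± 10.5 CPM (1.09 ± 0.21, adjusted p = 0.0108), Per3 by 0.88 ± 0.15, Tef by 0.75 ± 0.13 and Ciart by 0.94 ± 0.20. Nfil3, a repressor in the clock's output, also fell (-0.82, adjusted p = 0.021). The repressors Cry1 at -0.07, Cry2 at 0.32, Nr1d1 at 0.17 and Nr1d2 at 0.26 did not pass. Nfil3 and these repressors were named here after their values were seen. Arntl and Npas2 were lower, and Per2 higher, in each of the 10 mice than in every control mouse. The list as a whole had a median of 0.26 (adjusted p = 0.00219, but 0.647 with an estimated correlation) and a score higher by 0.21 (adjusted p = 0.0442, permutation).

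**Figure D3:**
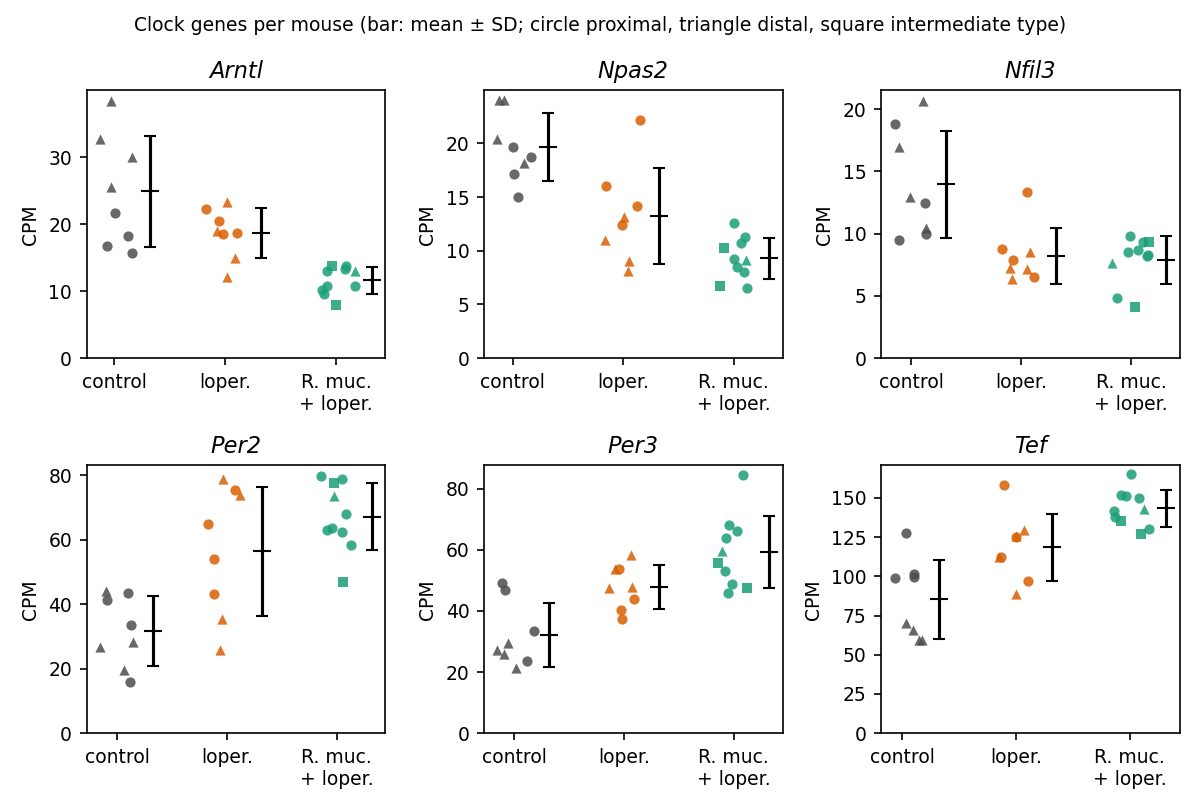
CPM of 6 clock genes in each mouse by group, with bars for the mean and SD and shapes for position type. The 10 R. mucilaginosa mice lie below every control mouse for Arntl and Npas2 and above every control mouse for Per2, with loperamide mice between by their means.

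Among proximal-type mice, 7 against 4, all 10 clock genes moved in the same direction and 4 passed: Arntl (-0.64 ± 0.16, adjusted p = 0.0292), Npas2 (-0.88 ± 0.17, adjusted p = 0.0135), Per3 (0.68, adjusted p = 0.0308) and Tef (0.46, adjusted p = 0.0286). With position as a covariate all 10 kept their calls. The loperamide group already lay between the others: 7 clock genes passed between loperamide and normal control, and 4 between R. mucilaginosa and loperamide, when adjusted over the list alone, against 0 over all genes in each.

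Goblet cell genes as a list were lower with R. mucilaginosa plus loperamide than in normal control. The list had a median of -0.28 (adjusted p = 0.00173, but 0.894 with an estimated correlation), with 2 of 21 genes past the threshold and 3 when adjusted over the list alone. Its score was 9.09 to 9.52 in distal-type and 8.62 to 9.25 in proximal-type control mice, against 8.76 to 9.11 in the proximal-type mice with R. mucilaginosa. That group held 1 distal-type mouse, so part of the list difference may follow position. Zg16 (ENSMUSG00000049350, chromosome 7, 127050156 to 127087328), a mucus lectin that binds bacteria, fell from 1785 ± 266 CPM (SD, n = 8) to 953 ± 286 CPM (n = 10), or by -0.91 ± 0.16 (adjusted p = 0.00753), and was lower than in every control mouse in 9 of 10. Tff3 (ENSMUSG00000024029, chromosome 17, 31125306 to 31129646), a goblet cell peptide of mucosal repair, fell from 298 ± 81.7 to 155 ± 57.0 CPM (-0.94 ± 0.21, adjusted p = 0.0227). Muc2, the main mucin, was at 20890 ± 8866 and 22440 ± 3814 CPM (0.10 ± 0.26, adjusted p = 0.866). The tight junction list was not called by camera (-0.03, 8 of 18 genes positive, adjusted p = 0.213), but its score was lower by -0.14 (adjusted p = 0.0282, permutation), with 1 gene, Cldn23, past the threshold (-0.58 ± 0.13, adjusted p = 0.0225) and 4 when adjusted over the list alone. The pan-epithelium list had a median of -0.18 with 1 of 18 genes positive (adjusted p = 0.00173, but 0.898 with an estimated correlation). Among proximal-type mice, Zg16 (-0.79 ± 0.22, adjusted p = 0.0419), Tff3 (-0.89, adjusted p = 0.0414) and Cldn23 (-0.69, adjusted p = 0.0127) kept their calls. Tff3 lost its call without normal control mouse 1 (-0.86, adjusted p = 0.0505) or 3 (-0.89, adjusted p = 0.0522) or R. mucilaginosa mouse 3 (-0.92, adjusted p = 0.0502).

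Stem cell genes were higher with R. mucilaginosa plus loperamide: the score was 4.68 ± 0.16 (SD, n = 8) in normal control, 4.86 ± 0.19 (n = 8) under loperamide and 4.98 ± 0.14 (n = 10) with R. mucilaginosa. The difference of 0.29 from normal control passed the permutation test (adjusted p = 0.0297), and camera gave a median of 0.16 (adjusted p = 0.00173, but 0.647 with an estimated correlation). Ascl2 (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264), a master regulator of intestinal stem cells, was the 1 of 11 genes past the threshold (4.13 to 7.16 CPM, 0.79 ± 0.18, adjusted p = 0.022), and 2 passed when adjusted over the list alone. Among proximal-type mice the list median was 0.36 (adjusted p = 8.4e-05, but 0.246 with an estimated correlation) and Ascl2 0.94 (adjusted p = 0.0292).

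The heat shock chaperones Hsph1 and Hspa1b were higher. Hsph1 (ENSMUSG00000029657, chromosome 5, 149614287 to 149636376) rose from 73.8 ± 17.6 CPM (SD, n = 8) to 179 ± 54.8 CPM (n = 10), or by 1.28 ± 0.20 (adjusted p = 0.00386), and stood at 135 ± 39.4 CPM under loperamide. Hspa1b, an HSP70 gene with a near-identical copy, Hspa1a, with which its reads could be shared, rose from 24.95 ± 8.99 to 57.4 ± 22.5 CPM (1.20 ± 0.26, adjusted p = 0.0213). Jun, an immediate early transcription factor, was lower (-0.49 ± 0.13, adjusted p = 0.0451). The list that holds these 3 was not called (-0.13, adjusted p = 0.513), and 5 of its 18 genes passed when adjusted over the list alone. Among proximal-type mice Hsph1 stood at 1.37 (adjusted p = 0.0192).

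Mitochondrial and lipid metabolism genes were lower. Oxidative phosphorylation had a median of -0.15 (adjusted p = 0.00272), mitochondrially encoded genes -0.27 (adjusted p = 0.00568), cholesterol synthesis -0.16 (adjusted p = 0.0251) and fatty acid oxidation -0.18 (adjusted p = 0.0417). mt-Nd5, a subunit of complex I encoded in the mitochondrion, fell from 2905 ± 1118 CPM (SD, n = 8) to 1608 ± 317 CPM (n = 10), or by -0.85 ± 0.17 (adjusted p = 0.0117). Interferon response genes had a median of 0.69 with 22 of 22 positive (adjusted p = 0.00401), antimicrobial defence -0.42 (adjusted p = 0.0459) and adipose tissue -1.58 (adjusted p = 0.0417). These 7 lists lost their calls with an estimated correlation (adjusted p = 0.898 with an estimated correlation for 6 of them and 0.751 for antimicrobial defence). Normal control mouse 1 carried part of this: its adipose score was 7.49 and its mitochondrial share 7.40 %, and without it the adipose median was 0.61, the mitochondrial one -0.04 (adjusted p = 0.182), fatty acid oxidation -0.10 (adjusted p = 0.223) and oxidative phosphorylation -0.09 (adjusted p = 0.0512). Antimicrobial defence lost its call without 10 of the 18 mice in turn (-0.52 to -0.35), fatty acid oxidation without 7 (-0.19 to -0.08), adipose tissue without a further 7 (-1.52 to -1.45) and cholesterol synthesis without 6 (-0.15 to -0.11). With composition covariates the calls of cholesterol synthesis (-0.12, adjusted p = 0.194) and antimicrobial defence (-0.34, adjusted p = 0.071) were lost, and with a position covariate that of cholesterol synthesis (-0.11, adjusted p = 0.405). Among proximal-type mice oxidative phosphorylation stood at -0.28 (adjusted p = 7.64e-08, but 0.539 with an estimated correlation), antimicrobial defence at -0.55 (adjusted p = 0.0105, but 0.426 with an estimated correlation) and interferon at 0.05 (adjusted p = 0.904).

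In all, 356 of 16868 genes passed between R. mucilaginosa plus loperamide and normal control, 150 higher and 206 lower, with a median absolute log2 fold change of 0.41 and 35 genes changed at least 2-fold. The balance of directions depended on scaling: 86.0 % of the genes called were higher when scaled by total counts only and 52.6 % by upper quartile. DESeq2 called 672 genes and limma 1185, and 3133 had an unadjusted p under 0.05 in edgeR. Further genes with large falls were Carmn, a smooth muscle long non-coding RNA (-2.01 ± 0.47, adjusted p = 0.0264), mt-Tn, a mitochondrial tRNA gene (-1.91 ± 0.46), Sprr1a, an epithelial stress protein (-1.71 ± 0.40), and Areg, an epidermal growth factor receptor ligand (-1.41 ± 0.38). At 71 bases mt-Tn is shorter than the 150 bp reads, and the RNA was poly-A selected, so its counts need not measure the tRNA itself. Agbl2 (-1.32 ± 0.33), Duoxa1, a maturation factor of the hydrogen peroxide producing oxidase DUOX1 (-1.28 ± 0.34), Plb1 (-1.16 ± 0.30), Frmd3 (-1.15 ± 0.27) and Ceacam2, an adhesion molecule with a close paralog (-1.11 ± 0.29), fell as well. Insrr, an alkali-sensing receptor of the insulin receptor family (1.25 ± 0.31), Mroh6 (1.17 ± 0.31), Fam129c (0.99 ± 0.26), Cys1, a cilium protein (0.98 ± 0.14), and Hsd17b14, a steroid dehydrogenase (0.91 ± 0.23), rose. In other lists Arrb2, an arrestin that shuts off opioid receptors (0.50 ± 0.13), and Slc26a6, an anion exchanger (0.54 ± 0.14), rose, and Dnajb9 of the unfolded protein response (-0.48 ± 0.11) and Tiparp, a target of the aryl hydrocarbon receptor (-0.41 ± 0.10), fell. Of the 32 named genes past the threshold, 28 moved in the same direction from the control mean in all 10 mice, and the other 4 in 9. They were chosen for passing in these same mice, which favours such agreement. The number of genes called ranged from 123, without R. mucilaginosa mouse 3, to 502, without R. mucilaginosa mouse 4. Besides R. mucilaginosa mouse 3, 7 mice moved it by over 1.5 times when left out, to 152 (normal control 3), 153 (R. mucilaginosa 10), 183 (R. mucilaginosa 6), 206 (R. mucilaginosa 1), 208 (R. mucilaginosa 5), 216 (normal control 1) and 223 (normal control 2).

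Of the 32 named genes, 13 kept their calls in all 18 fits with 1 mouse left out: Arntl, Npas2, Per2, Per3, Tef, Ciart, Hsph1, Hspa1b, Zg16, Cldn23, Ascl2, Cys1 and mt-Nd5. In other settings 30 of the 32 kept their calls with a position covariate, 20 within proximal-type mice and 6 with a replicate block. Without loperamide mice 5 and 6 and normal control mouse 1, 20 did. Carmn lost its call without 3 mice, with -1.09 (adjusted p = 0.094) without normal control mouse 2, and mt-Tn without 4, with -1.33 (adjusted p = 0.1) without normal control mouse 1. Dnajb9 lost its call only without R. mucilaginosa mouse 3 (-0.45, adjusted p = 0.0502). Frmd3, Sprr1a and Agbl2 lost theirs without 4 to 6 mice in turn, and Jun, Areg, Ceacam2, Fam129c, Arrb2, Duoxa1, Slc26a6, Mroh6, Insrr, Hsd17b14, Tiparp and Plb1 without 9 or more. Among proximal-type mice, 7 against 4, the comparison called 964 genes, 339 higher and 625 lower, and 252 of the 356 were among them, all 356 with the same sign. With the position index as a covariate, 508 of the 964 stayed past the threshold (median log2 fold change 0.47 before and 0.46 after). With position as a covariate 1012 genes were called, 353 of the 356 among them. Exons of Duoxa1 (17.1 % of bases), Jun (7.28 %) and Tiparp (5.12 %) overlap genes on the other strand. With the strand setting not given, their counts could include reads of those genes. The same holds for Hdac4 (22.4 %), Ddx41 (17.4 %), Tspan4 (13.4 %), Rogdi (10.2 %), Cygb (8.62 %) and Muc13 (6.06 %). Exons of Fam129c (21.8 %) overlap a gene on the same strand, whose reads no strand setting would set apart.

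**Figure D4:**
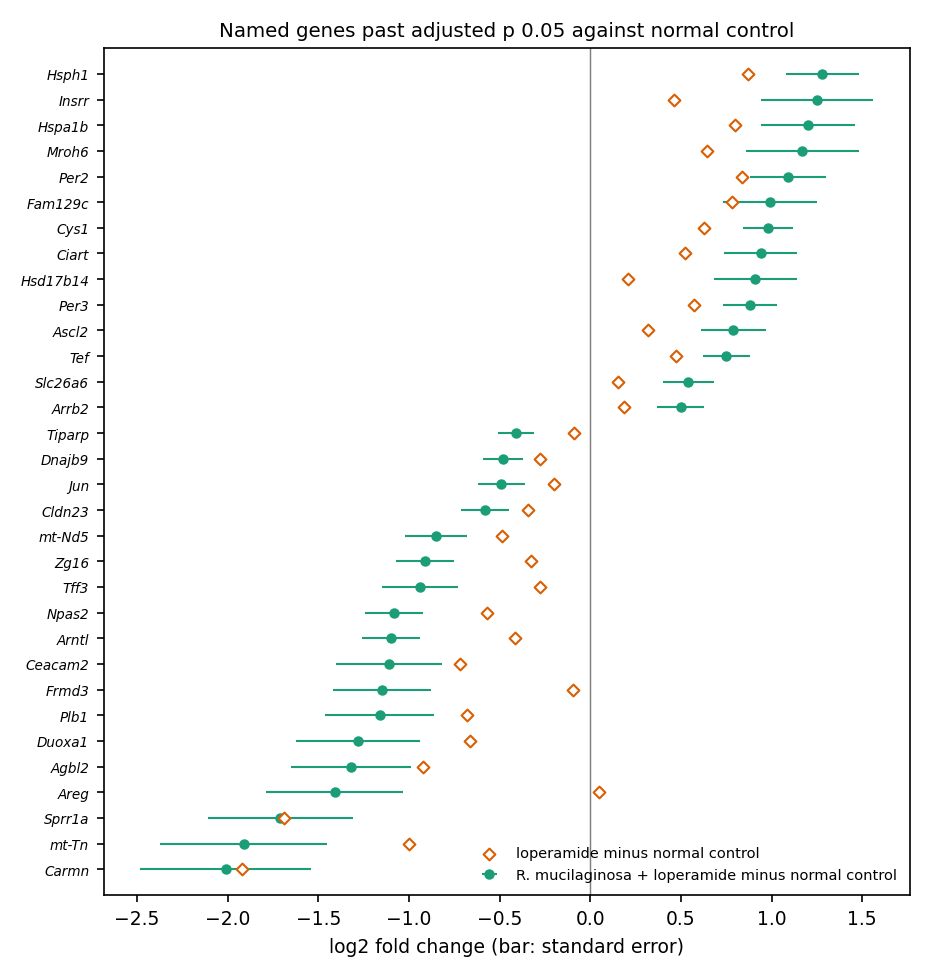
Log2 fold change of the 32 named genes past the threshold, R. mucilaginosa plus loperamide minus normal control (filled, bar: SE), beside loperamide minus normal control (open). Sprr1a and Carmn have nearly the same value in both, while Arntl is at -1.10 and -0.41.

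Key genes of gut movement, fluid and inflammation did not pass in any comparison. Against normal control with R. mucilaginosa, Aqp8, a water channel of colonocytes, had -2.19 ± 0.95 (adjusted p = 0.213), Ocln, a tight junction protein, -0.25 ± 0.08 (adjusted p = 0.102), Muc13, a membrane mucin, -0.28 ± 0.12 (adjusted p = 0.214) and Tnf, an inflammatory cytokine, -0.78 ± 0.34 (adjusted p = 0.22). Tjp1 had -0.17 ± 0.08, Aqp4 -0.59 ± 0.65, Il1b 0.17 ± 0.36, the pacemaker genes Kit 0.31 ± 0.17 and Ano1 -0.30 ± 0.31, and the glial Gfap 0.07 ± 0.42. The serotonin genes Tph1, Slc6a4, Htr4 and Htr3a lay between -0.22 and 0.42, the cholinergic Chat, Chrm2 and Chrm3 between -0.69 and 0.33, and the transmitter genes Nos1, Vip and Tac1 between -0.21 and 0.08. Under loperamide against normal control the 21 measured key genes lay between -0.67 (Aqp8) and 0.22 (Tph1), and with R. mucilaginosa against loperamide between -1.52 (Aqp8) and 0.57 (Chat). Ocln passed within proximal-type mice (-0.32, adjusted p = 0.0494) and without R. mucilaginosa mouse 8 (-0.29, adjusted p = 0.0388), and Ano1 changed sign within proximal-type mice (0.41). Oprm1, the mu-opioid receptor gene, Aqp3 and Il6 had too few counts to be tested.

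**Figure D5:**
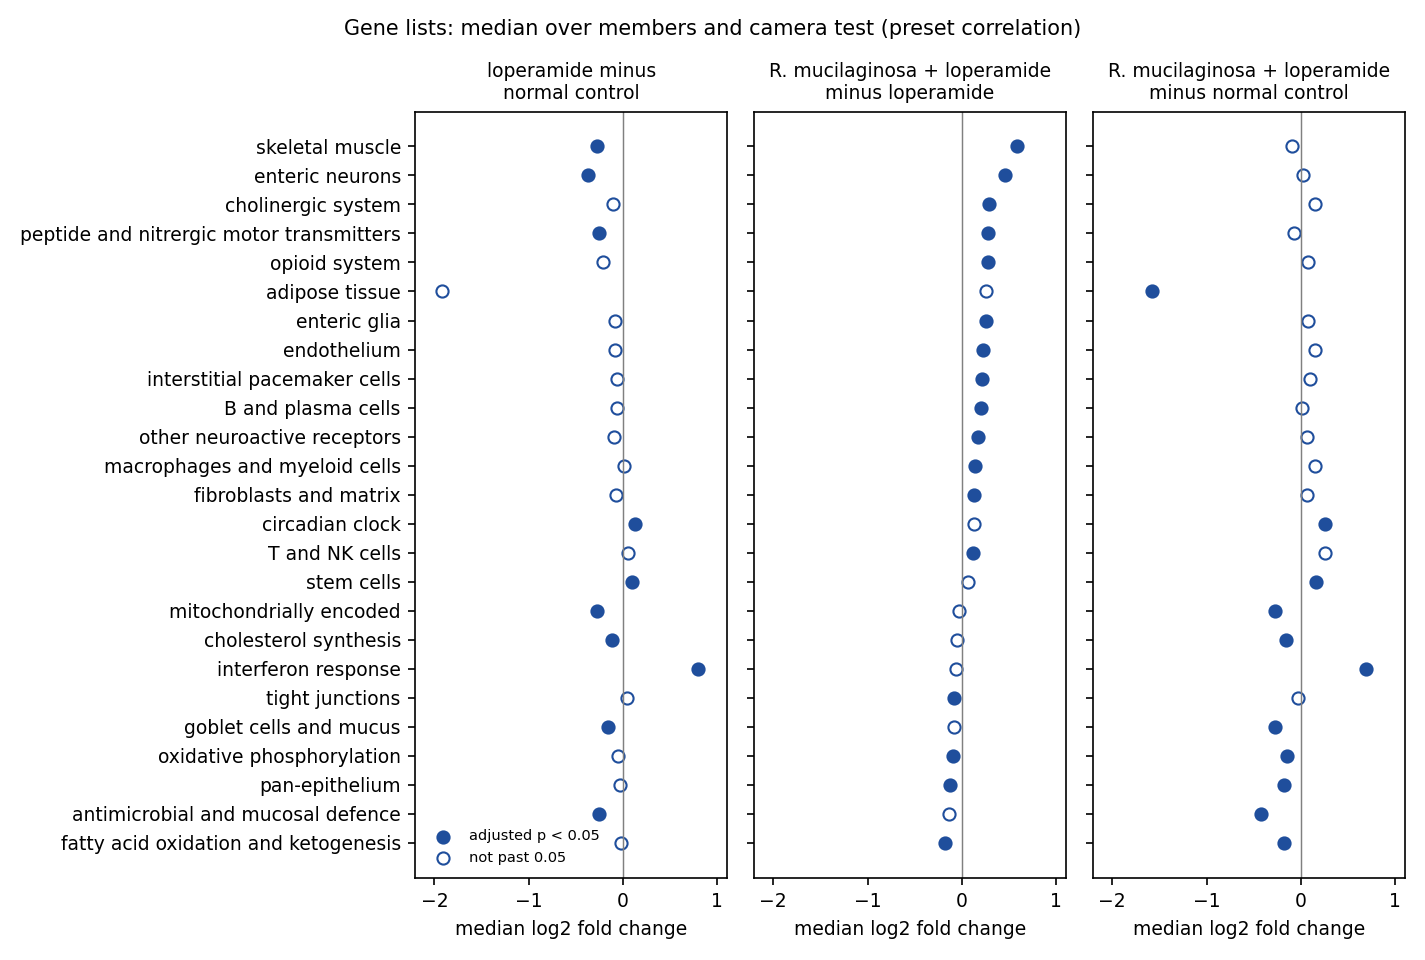
Median log2 fold change over the genes of each of the 25 lists called in at least 1 comparison, in 3 panels by comparison; filled points have a camera adjusted p under 0.05 at the preset correlation. Enteric neurons lie at -0.37 under loperamide and at 0.46 with R. mucilaginosa added, and at 0.02 against normal control.

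Of the 44 lists, 19 were called in no comparison, and their medians follow for loperamide against normal control, for R. mucilaginosa against loperamide and for R. mucilaginosa against normal control. In nerve, muscle and fluid lists these were -0.10, 0.15 and 0.00 for the serotonin system, -0.11, -0.05 and -0.16 for smooth muscle contraction, -0.01, 0.05 and 0.02 for smooth muscle calcium and rho signalling, -0.04, -0.08 and 0.18 for aquaporins, and 0.08, -0.13 and -0.17 for colonic ion transport. They were 0.05, 0.04 and 0.03 for enteroendocrine cells, 0.08, -0.08 and 0.08 for proliferation, -0.09, -0.02 and 0.05 for inflammatory cytokines, 0.04, 0.08 and 0.09 for antigen presentation, and -0.29, 0.20 and 0.03 for mast cells. Markers of neighbouring tissue gave -0.49, -0.14 and -0.49 for exocrine pancreas, 0.04, -0.08 and -0.11 for red blood cells, and -0.40, -0.13 and -0.53 for mesothelium. Only 3 of 13 pancreas genes and 2 of 7 mesothelium genes were measured, against 6 of 7 for red blood cells. The position lists gave 0.10, -0.11 and 0.06 for distal and 0.07, -0.44 and -0.45 for proximal genes. Stress and nutrient lists gave -0.02, -0.10 and -0.13 for immediate early and heat shock genes, -0.04, 0.03 and -0.02 for the unfolded protein response, -0.03, -0.16 and -0.21 for xenobiotic metabolism, and -0.12, -0.13 and -0.14 for fatty acid and bile acid sensing. The median, mean and test of a list differed in sign for 11, 6 and 6 lists in the 3 comparisons, none of them called.

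Whether R. mucilaginosa returned loperamide's changes towards control was asked across genes. No gene passed in both steps with edgeR, in the opposite or the same direction, since 0 passed in either (1198 and 1423 at an unadjusted p under 0.05, and 9 and 4 genes by DESeq2 and 0 by limma). The expected overlap of independent lists was 0. The log2 fold changes of both steps, which share the loperamide mice, had r = -0.356 and a covariance of -0.0258 across 16868 genes, which are not independent replicates. Simulated sets with no effect gave a mean r of -0.532 (-0.603 to -0.509) and a mean covariance of -0.031 (-0.0394 to -0.0284). Their genes were drawn independently of each other, unlike genes of the same mice, so these ranges may be too narrow. The observed r and covariance were both less negative than in every simulated set. With 1 loperamide mouse left out the observed r ran from -0.438 to -0.335 and the covariance from -0.0367 to -0.0238. These fits share most of their mice and give no range for chance. Whether the observed values lie outside chance therefore cannot be told. With separate loperamide mice for each step, the median r over 70 splits was 0.201 (-0.0503 to 0.514) and the median covariance 0.018, and 11 of the 70 were negative. The 36 of these splits with 2 distal-type mice on each side gave a median r of 0.057 and a median covariance of 0.00437, and held all 11. Of the 3 lists called in both steps, enteric neurons, transmitters and skeletal muscle, all 3 went in opposite directions, which the shared loperamide mice favour without any effect, and none held with an estimated correlation.

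The 356 genes that separate R. mucilaginosa plus loperamide from normal control mostly moved in the same direction in both steps. Of these, 353 had the same sign under loperamide alone and 349 the same sign when R. mucilaginosa was added, with median changes of 0.21 and 0.19 in that direction. The loperamide mean lay between those of the other groups for 346 genes, against a mean of 296 (283 to 314) of as many genes with the smallest p in simulated sets with no effect. The simulated genes were drawn independently of each other, unlike genes of the same mice, so this range cannot show an excess beyond chance. Of the lists, 7 were called both under loperamide and against normal control, 0 of them in opposite directions: antimicrobial defence, cholesterol synthesis, clock, goblet cells, interferon, mitochondrially encoded and stem cells. Both comparisons share the control mice, which favours the same direction without any effect, and none of the 7 held with an estimated correlation.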

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

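The tests of splits, position, single mice, pairs of mice, exchanged labels, neurons against muscle and the clock index in this part were chosen after the results were seen.

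The first pattern is the 356 genes that separated R. mucilaginosa plus loperamide from normal control. A chance division of the mice is argued against: of 100 splits of these 18 mice, only the real one gave as many, and the highest other gave 39. Position along the colon as the whole cause is argued against too, since 353 of the 356 genes stayed past the threshold with position as a covariate. For the 964 genes called among proximal-type mice it cannot be told apart. With that covariate 508 of the 964 stayed past the threshold, while all 964 kept their sign and their median log2 fold change went from 0.47 to 0.46. Of 100 splits of the proximal-type mice only the real one gave as many as 964, with 720 as the highest other, which bears on chance and not on position. That other split, which exchanged R. mucilaginosa mouse 4 with normal control mouse 4, points to a structure among these mice, and the count over all mice but that mouse was 502. A single mouse as the cause is argued against by the fewest genes called with any 1 left out, 123 without R. mucilaginosa mouse 3, which is above the 39, while loperamide, the bacterium, cage and batch all differ or may differ between these groups and stay open.

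The second pattern is the clock, in which Arntl and Npas2 fell while Per2, Per3, Tef, Dbp, Hlf and Ciart rose. Position as its whole cause is argued against, because 10 of 10 clock genes kept their call and direction with position as a covariate. Among proximal-type mice all 10 kept their direction but only 4 their call, so a part for position is not excluded. A clock index, the mean log2 CPM of the Per, Rev-erb and PAR bZIP genes, Ciart and Bhlhe41 minus that of Arntl, Clock, Npas2 and Nfil3, differed by 1.39 between R. mucilaginosa plus loperamide and normal control (exact permutation p = 2.29e-05, adjusted p = 0.00016 over 7 tests), by 0.95 among proximal-type mice (p = 0.00303), and by 1.27 over all mice with Cry1, Cry2 and Bhlhe40 added. The index was formed after the directions of these genes were seen, so its p-values restate that opposed shift and do not test it anew. A later collection of the treated mice could give such an opposed shift, although Cry1 (-0.07) and Nr1d1 (0.17) did not pass, and so could a shift of the colon's clock by loperamide, the bacterium or altered feeding. These cannot be told apart, because the collection times are not given and the groups could differ in them.

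The third pattern is the 669 genes called between R. mucilaginosa plus loperamide and loperamide among proximal-type mice, in which neuron, muscle and connective tissue lists were higher and epithelial lists lower. None of the lists called there held with an estimated correlation. Chance division alone is argued against, as 2 of 100 splits gave as many, the real one included, but the other gave 1697 by exchanging loperamide mouse 8 with R. mucilaginosa mouse 4, which points to a structure among the mice, while exchanged labels are argued against by the clock index of mouse 8, 0.31, which is below the lowest of the other 9 R. mucilaginosa mice by -0.85 (their SD 0.27), although mouse 4, at 0.98, also lay within the 0.33 to 1.33 of the other 7 loperamide mice. Position cannot be told apart: with the position index as a covariate 9 genes stayed past the threshold, although the median log2 fold change of the 669 went only from 0.51 to 0.49, with the SE up from 0.12 to 0.14. That fit may lean on loperamide mouse 6, whose index of -10.02 rests on 0 Hoxa13 counts, while the other proximal-type loperamide mice lay at -5.99 to -5.45. A smaller share of the muscle wall in the loperamide samples may account for part. Neuron and smooth muscle scores were both higher with R. mucilaginosa, by 1.21 (exact permutation p = 0.0303) and 0.82 (p = 0.0455), and their difference of 0.39 was within its spread (p = 0.109). Loperamide mice 5 and 6, with neuron scores of 0.98 and 0.12, may carry part of it, since without both 0 genes were called by edgeR (1496 at an unadjusted p under 0.05), but pairs 2 and 5, 2 and 6, and 5 and 8 gave 0, 1 and 72, while 2 and 8 gave 2054 and 6 and 8 gave 2087, so the smaller number of mice alone does not bring the count to 0 and for the count the part of mice 5 and 6 cannot be told apart from that of mice 2 and 8, while the neuron median was 0.29 without 5 and 6, which were chosen for low neuron scores, against 0.64 to 2.28 without the other pairs. An effect of the bacterium on neurons stays open, since over all mice, with covariates for muscle against epithelium and for position, the enteric neuron median fell from 0.46 to 0.15 (adjusted p = 0.0342), and the call without covariates was lost with an estimated correlation (adjusted p = 0.669).

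Between loperamide and normal control, and between R. mucilaginosa plus loperamide and loperamide, edgeR called 0 genes with all mice (1198 and 1423 at an unadjusted p under 0.05, DESeq2 9 and 4, limma 0 and 0), and with 0 called, all 100 splits had to give at least as many, so the splits say nothing about chance. For the first, the highest other split gave 1767 genes. The 4 splits with the most genes, 102 to 1767, each placed 6 or 7 of the 8 distal-type mice on one side, which points to position as a structure of the samples, and all other splits gave 14 genes or fewer. Within proximal-type mice the comparison gave 0 genes and within distal-type mice 1. For the second, the highest other split gave 20.

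Of 354 sets of values, each a measure within a group, 35 held a mouse far from the others, against 18 expected by chance, and R. mucilaginosa mouse 8 (7 values), normal control mouse 1 (6) and loperamide mouse 8 (6) stood apart most often. Normal control mouse 1 was highest in its group for total counts (21.3 M), the mitochondrial share (7.40 %), the adipose (7.49), endothelium (4.71) and mitochondrially encoded scores (11.6) and log2 CPM of mt-Nd5 (12.4). Loperamide mouse 6 was lowest for smooth muscle contraction (4.91), smooth muscle calcium and rho signalling (3.67) and Vip (1.57). Loperamide mouse 8 was highest for inflammatory cytokines (3.67), macrophages (4.95) and Nfil3 (3.75), and lowest for Tjp1 (7.26), Map2k6 (3.71) and Plb1 (-1.28). R. mucilaginosa mouse 8, the only distal-type mouse of its group, was lowest for other neuroactive receptors (2.06), the proximal position list (4.83), fatty acid and bile acid sensing (4.05), Vip (4.39), Insrr (1.75) and Agbl2 (-1.96), and highest for proliferation (6.14).

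Normal control mouse 7 was highest for colonic ion transport (7.31) and lowest for B and plasma cells (3.50) and the unfolded protein response (5.59). Normal control mouse 6 was highest for tight junctions (6.33) and lowest for Zc3h12a (4.91). Normal control mouse 4 was lowest for Pde10a (0.923). R. mucilaginosa mouse 2 was highest for inflammatory cytokines (3.36) and antigen presentation (7.42). R. mucilaginosa mouse 4 was highest for mast cells (1.66) and Pde10a (1.97). R. mucilaginosa mouse 7 was lowest for the circadian clock (4.95) and R. mucilaginosa mouse 6 for Plb1 (-1.91), and loperamide mouse 4 was lowest for Ciart (1.75).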

How the results depend on the processing

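The fits with a position covariate, within 1 position type and without 3 mice were chosen after the data were seen. All others were planned. The cause of a change was not tested except where the setting itself gives it, as fewer mice or genes do.

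Between loperamide and normal control the count of 0 genes (edgeR, 1198 at an unadjusted p under 0.05) became 9 with DESeq2, 99 with an unadjusted p and 2-fold, 1 within distal-type mice and 0 to 3 with 1 mouse left out, and stayed 0 with limma and 10 other planned settings. The 10 lists became 0 with an estimated correlation and 6 to 17 with 1 mouse left out. Between R. mucilaginosa plus loperamide and loperamide the count of 0 genes (edgeR, 1423 at an unadjusted p under 0.05, limma 0) became 4 with DESeq2, 75 with an unadjusted p and 2-fold and 669 within proximal-type mice, and was 0 with each mouse left out and within proximal-type mice without the 3. The 17 lists became 0 with an estimated correlation, 12 with composition covariates (9 shared, with all nerve lists but neurons lost), 8 without the 3 mice (4 shared) and 14 to 22 with 1 mouse left out.

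Against normal control, the 356 genes with R. mucilaginosa became 743 with scaling by total counts only (254 shared, 86.0 % higher against 42.1 %, with the median of all genes at 0.09), 149 with no filter (143 shared), 672 with DESeq2 (335 shared), 1185 with limma (352 shared), 586 with composition covariates (347 shared), 35 with a 2-fold minimum and 136 with an unadjusted p and 2-fold. Upper quartile scaling gave 348 genes, 52.6 % of them higher. The count was 1012 with a position covariate (353 shared), 964 within proximal-type mice (252 shared), 212 within these without the 3 mice (91 shared) and 123 to 502 with 1 mouse left out. The 11 lists became 0 with an estimated correlation, 18 within proximal-type mice without the 3 and 8 to 12 with 1 mouse left out.

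With a replicate block, which compares 8 numbers per group, the 356 genes became 28, all 28 shared. The interferon median became 0.14 under loperamide (adjusted p = 0.165) and 0.18 against normal control (adjusted p = 0.101), adipose against normal control -0.02 (adjusted p = 0.137), and the clock under loperamide lost its call (0.13, adjusted p = 0.0616). The numbers do not pair the mice: correlations over 0.1 were seen in 2, 2 and 3 of 8 pairs in the 3 comparisons, and 0, 0 and 1 mouse correlated best with its own number. The counts of 0 genes stayed 0 (edgeR, 945 and 849 at an unadjusted p under 0.05).

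Directions that changed within proximal-type mice without the 3 were, under loperamide, transmitters 0.22, neurons 0.33, clock 0.03 (in the test's direction only) and Aqp4 -0.85, between R. mucilaginosa and loperamide B cells 0.00, T cells -0.69, macrophages -0.05 and Aqp4 0.96, and against normal control adipose 0.89, mitochondrially encoded 0.05 and Ano1 0.36. Within all proximal-type mice T cells were at -0.35 and Ano1 at 0.52 between R. mucilaginosa and loperamide, and interferon at 0.05 and Ano1 at 0.41 against normal control. Within distal-type mice cholesterol synthesis under loperamide was at 0.01. Without the 3 mice neurons under loperamide were at -0.05, with the test pointing up, and adipose against normal control at 0.62. With 1 mouse left out the interferon median under loperamide ran from -0.04 to 1.16 and adipose against normal control from -1.84 to 0.61. The mitochondrial score difference between R. mucilaginosa and loperamide was -0.19 as a median over members. A further 152 of 5521 sign changes lay within the error of both fits. Across genes, r of both steps was -0.496 within proximal-type mice and -0.438 to -0.335 with 1 mouse left out, and the covariance -0.0802, -0.0367 to -0.0238, and -0.0129 over genes of at least 5 CPM.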

Other observations

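The tests within position types and of the clock index in this part were chosen after the results were seen, and its genes follow the rule for named genes.

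Epithelial transport and detoxification genes were lower with R. mucilaginosa than with loperamide alone among proximal-type mice, 7 against 4. In the same mice the smooth muscle score was higher with R. mucilaginosa, by 0.82 (exact permutation p = 0.0455). A different share of tissues in the samples therefore cannot be told apart from a change within the epithelium. Colonic ion transport genes had a median of -0.35 (adjusted p = 0.000705, but 0.187 with an estimated correlation), and 4 of its genes fell, among them Sgk1, a kinase of sodium uptake (-1.78 ± 0.43 SE, adjusted p = 0.0316), Best2, a bicarbonate channel of goblet cells (-2.25 ± 0.48, adjusted p = 0.0194), and Nr3c2, the aldosterone receptor (-0.50 ± 0.14, adjusted p = 0.0412). Xenobiotic metabolism genes had a median of -0.54 (adjusted p = 3.71e-07, but 0.187 with an estimated correlation), with 5 lower, such as the efflux pump Abcg2 (-1.20 ± 0.32, adjusted p = 0.0402) and Nqo1, a quinone reductase (-0.77 ± 0.18, adjusted p = 0.0268). Genes of serotonin handling that fell were Maoa, which breaks serotonin down (-1.09 ± 0.25, adjusted p = 0.0244), and Ddc, which makes it (-0.61 ± 0.17, adjusted p = 0.0464). The comparison called 0 genes by edgeR without loperamide mice 5 and 6 (1496 at an unadjusted p under 0.05), and also without mice 2 and 5 (2290), and 9 genes with the position index as a covariate, where all 669 kept their sign and their median log2 fold change went from 0.51 to 0.49.

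Against normal control, proximal-type mice with R. mucilaginosa also had lower xenobiotic metabolism (-0.41, adjusted p = 5.84e-05) and fatty acid and bile acid sensing genes (-0.41, adjusted p = 0.0129), both with adjusted p = 0.426 with an estimated correlation, and higher smooth muscle contraction genes (0.39, adjusted p = 0.00789, but 0.885 with an estimated correlation).

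The clock index followed position in normal control, with -0.66 to -0.25 in distal-type and 0.10 to 0.75 in proximal-type mice. It was 0.58 ± 0.26 (SD, n = 4) under loperamide and 0.41 ± 0.29 (n = 4) in normal control among proximal-type mice, a difference of 0.18 (exact permutation p = 0.4, adjusted p = 0.4). Among distal-type mice the same difference was 1.31 (exact permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0334). R. mucilaginosa exceeded loperamide by 0.65 over all mice (exact permutation p = 0.00064, adjusted p = 0.00224) and by 0.78 among proximal-type mice (exact permutation p = 0.00303, adjusted p = 0.0053), and exceeded normal control by 0.95 among proximal-type mice (exact permutation p = 0.00303, adjusted p = 0.0053). Since the index was formed after the directions of its genes in these mice were seen, its p-values describe the shift and do not test it anew. Whether the loperamide difference differs between position types was tested gene by gene only, with 0 genes past the threshold by edgeR (613 at an unadjusted p under 0.05).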
